A study of Oryza sativa with 80 samples.

How the data were processed

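Poly(A) RNA was measured in the third leaf, when mature, of rice (Oryza sativa) seedlings grown in soil held at 3 g water per g dry soil (well-watered) or 1.5 g/g (a drought that limits growth) and collected at 30 °C or after a heat shock of 30 min at 40 °C. The groups are called W30, D30, W40 and D40, after the soil water (W or D) and the temperature. Segments 2 (nearest the base) to 6 (nearest the tip) of the leaf blade were sequenced separately. Per the labels' protocols, each replicate held matched segments of 3 leaves, so the 80 libraries came from 16 leaf pools, 4 per treatment, and the pool rather than the library was the unit of replication. Well-watered leaves were collected at 10 days and drought leaves at 12 days, so leaf age differed along with soil water. The labels also give a batch. Batch 1 held 7 pools and batch 2 held 9 pools, and W40 had 1 pool in batch 1.

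The submitters' processing notes name HISAT2 2.2.1, featureCounts 2.0.6 and Picard 3.1.0. The genome build is not given in the sources used here. The authors deposited raw gene counts, batch-corrected gene counts and batch-corrected FPKM values, one column per library, per the file headers. The batch-corrected counts deposited by the authors are estimated counts that were rounded to whole numbers here before any test, and how the correction was made is not given in the sources used here. The count tables held 42189 genes, of which 42004 had MSU locus IDs, and the FPKM table held 42102. Of the raw counts from 1 to 20, 76.9% were even, as they would be if both reads of most pairs were counted, so raw counts overstate the number of independent fragments. Among the raw counts, 0 entries lacked a gene ID. The FPKM values deposited by the authors followed the batch-corrected counts, scaled to the library total and divided by a length, to within 1% in 100% of the values tested, and were therefore used only in an alternative.

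Library totals ran from 53398019 to 76741242 counts in batch 1 and from 60300951 to 128636996 in batch 2. Each library differed from the others of its group by more than sampling noise: the lowest chi-square per degree of freedom between 2 libraries of a group was 9.57 over 120 pairs.

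Raw counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10 and minimum total of 15, quasi-likelihood F tests) and Benjamini-Hochberg adjustment, with adjusted p under 0.05 as the threshold. Whole-leaf comparisons summed the 5 segments of each pool and fitted treatment and batch to the 16 pools. Comparisons within a segment fitted the same terms to the 16 libraries of that segment. Tests between segments fitted leaf pool as a block, with segment by treatment, to all 80 libraries. Within a treatment the replicate numbers pair the segments of a pool by the labels' protocols, and deviations of same-pool segments had a median correlation of 0.38, against -0.21 for segments of different pools. Gene lists were tested with camera (2-sided) in limma 3.58.1 on voom values of the pool sums, with a preset inter-gene correlation of 0.01 and with an estimated correlation beside it. Adjusted p-values printed for genes come from edgeR, and those printed for lists from camera, adjusted over the lists of a comparison. Standard errors printed for genes were derived as the absolute log2 change divided by the square root of the F statistic. They are approximate, above all for loci near 0 in a group. CPM values (counts scaled to the library total) are TMM-scaled.

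The files give locus IDs without names, and 0 of these IDs were found in the RefSeq gene table at hand, so no gene symbol is printed. The gene lists are 65 locus IDs entered by hand from general knowledge, together with the name of the list each belongs to, before the data were examined. No table used here checks these assignments, and a list name therefore describes what its members were entered as. Of the 65 loci in 13 lists, 64 passed the expression filter in whole leaves, and the only locus of the meristem homeobox list did not, so that list was not tested. The osmolyte list held 1 locus, which was tested as a gene only. Lists planned from product descriptions were dropped, as planned for the case that no descriptions exist. Other groups put together from recalled IDs after the data had been looked at were also left out. The rule for named loci allowed, per list and comparison, up to 4 members with the smallest adjusted p (up to 3 in tests between segments), any chaperone or heat stress transcription factor on the lists, and per comparison at most 2 IDs each way with the largest fold change among genes with adjusted p under 0.05, mean CPM of at least 5 and groups that did not overlap. Reads shared between near-identical members of a gene family could be split between them by the counting, so values of the neighbouring small heat shock protein loci and of the neighbouring dehydrin and LEA loci are uncertain.

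The procedure was tested on simulated counts for the real genes. With known changes put in, the edgeR test of heat in well-watered leaves recovered 36% of 100 genes changed by 1 log2 unit and 80% of 100 genes changed by 2, among 24853 genes. For the drought by heat interaction, over 24857 genes, it recovered 7.07% and 64.7% of 99 genes each. Estimates were near the truth, with a median ratio of 1.04 for heat and 0.98 for the interaction at 2 log2 units. The simulated changes were the same in both batches, whereas many real responses differed between batches. The simulation therefore does not show how estimates or false calls behave in that case. Of the genes called in the heat simulation, 9.38% were false, above the nominal 5%. A first requirement of more than 80% recovery was narrowly missed by the heat simulation and was replaced, after its result was seen, by one on the estimates. Alternatives planned before the data were examined were DESeq2 1.42.0 size factors and Wald test, no filter, no batch term, the batch-corrected counts and FPKM (log2 with a pseudocount of 1), a replicate block, single batches, other fits and leaving out each pool. Treatment by batch cell means, halved counts, thinned pools, single batches in the tests within and between segments, and a segment by batch term were added after seeing the data. Single pools left alone in a batch and treatment were assumed to vary like the others. Other splits of the pools were counted with limma voom.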

Results

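The series measured gene expression along the third leaf of rice, when mature, under heat shock, growth-limiting drought and both together. Its title asks how such drought alters the sensitivity of the leaf to heat. There were 20 groups of 4 libraries, from 4 treatments and 5 leaf segments. Library totals ran from 53398019 to 128636996 counts, and the sums per leaf pool from 310494791 to 513401279. In a principal component analysis the first component held 34.3% of the variance. Taken singly, batch accounted for 53.7% and temperature for 47.3% of its spread. The second component held 16.7%, and soil water accounted for 68.5% of its spread. Counts within each batch are therefore given beside the pooled ones for whole leaves. Batch 1 held 1 W40 pool, which was assumed to vary like the others. Loci are described by the list they were entered under, which no annotation table used here could check.

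Heat shock of well-watered leaves raised the loci listed as chaperones, which bind unfolding proteins. All 4 members of the HSP90 and HSP100 list, both HSP70 members and 5 of 6 small heat shock protein members rose, the last count being 6 when adjusted over the list alone. Of 9 heat stress transcription factors, a family that regulates heat shock genes, 7 rose and the other 2 fell. The small heat shock protein LOC_Os02g52150 rose from 4.26 ± 2.81 CPM (SD, n = 4) to 3054 ± 1270 CPM. LOC_Os08g39140 of the HSP90 and HSP100 list rose from 47.4 ± 10.2 to 6457 ± 2760 CPM (SD, n = 4), a log2 change of 6.54 with a standard error of 0.51 (edgeR adjusted p = 1.85e-06). LOC_Os05g38530 of the HSP70 list changed by 7.33 (standard error 0.36) and the transcription factor LOC_Os09g35790 by 5.79 (standard error 0.24). With camera the lists of small heat shock proteins, HSP90 and HSP100 chaperones and HSP70 chaperones lay above other genes, each at adjusted p = 0.0423 with an estimated correlation. The transcription factor list had adjusted p = 8.76e-05 with the preset correlation and adjusted p = 0.192 with an estimated correlation. In batch 1 and batch 2 taken alone, 5 and 6 small heat shock protein loci, 3 and 4 HSP90 and HSP100 loci and both HSP70 loci rose. Of the transcription factors 5 rose in batch 1, and 7 rose and 1 fell in batch 2. The heat response differed between batches for 5 small heat shock protein loci, 3 HSP90 and HSP100 loci, 4 transcription factors and no HSP70 locus. LOC_Os08g39140, 1 of these, changed by 5.87 in batch 1 and 7.40 in batch 2 (log2). LOC_Os02g52150 was at 1248 CPM in the W40 pool of batch 1 and at a mean of 3656 CPM in the 3 of batch 2.

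Single loci of other lists also changed with heat in well-watered leaves, and of these lists only the clock list was called with an estimated correlation. Of the 7 circadian clock members, which belong to the oscillator that times daily gene expression, 4 fell and none rose, or 6 were called when adjusted over the list alone. The clock locus LOC_Os02g40510 went from 116.6 ± 90.7 to 30.3 ± 43 CPM (SD, n = 4). It was at 191.1 and 199 CPM in the W30 pools of batch 1 and at 37.7 and 38.4 CPM in those of batch 2. The clock list lay below other genes, with adjusted p = 0.0096 and adjusted p = 0.0423 with an estimated correlation. Of 11 abscisic acid loci 7 rose, with list adjusted p = 0.018 and adjusted p = 0.578 with an estimated correlation. Of 7 dehydrin and LEA loci 1 rose and 1 fell: LOC_Os02g44870 went from 8.05 ± 4.41 to 100.1 ± 19.1 CPM (SD, n = 4). Of 9 drought regulators 4 rose, or 6 were called when adjusted over the list alone. The chlorophyll breakdown locus LOC_Os03g21060, 1 of 2, fell from 5.13 ± 2.75 to 2.02 ± 0.387 CPM (SD, n = 4), and 1 of 3 secondary wall loci fell at levels below 1 CPM. The dehydrin and LEA, drought regulator, chlorophyll breakdown and secondary wall lists were not called by camera with the preset correlation (adjusted p = 0.431, 0.127, 0.526 and 0.431). None of the 3 Calvin cycle loci and not the osmolyte locus passed the threshold. In batch 1 alone 3 clock loci fell and 6 abscisic acid loci, 1 dehydrin and LEA locus and 1 drought regulator rose. In batch 2 alone 5 clock loci fell, and 10 abscisic acid loci, 3 dehydrin and LEA loci and 5 drought regulators rose while 1 of each of these 3 lists fell. The osmolyte locus rose and 1 chlorophyll breakdown and 1 Calvin cycle locus fell in batch 2, with none of these called in batch 1, and no secondary wall locus was called in either batch. The response of 5 abscisic acid, 3 clock and 2 drought regulator loci differed between batches. Among all genes, LOC_Os02g34270 had 0 counts in the 4 W30 pools and 18.6 ± 13.7 CPM (SD, n = 4) in W40. The W40 mean, though not each pool, was at least 10600-fold higher with a floor of 3 counts over the W30 pools. LOC_Os08g26710 fell from 37 ± 5.51 to 1.43 ± 1.36 CPM (SD, n = 4). In whole leaves 8801 of 25103 genes differed between W40 and W30, 4098 higher and 4703 lower, and limma on the batch-corrected FPKM gave 2788 higher and 6766 lower. The counts were 3308 in batch 1 and 13478 in batch 2.

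Heat shock of drought leaves raised all 6 small heat shock protein loci, all 4 HSP90 and HSP100 loci and both HSP70 loci. Of the 9 heat stress transcription factors 6 rose and 1 fell. LOC_Os01g04380, a small heat shock protein, went from 1.42 ± 1.13 to 924.8 ± 986 CPM (SD, n = 4), and LOC_Os08g39140 from 70.3 ± 23.5 to 7349 ± 6260 CPM (SD, n = 4). The D40 pools parted by batch: LOC_Os08g39140 was at 1843 and 2069 CPM in batch 1 and at 11910 and 13570 CPM in batch 2. The 3 chaperone lists had adjusted p = 0.0488 each with an estimated correlation. The transcription factor list had adjusted p = 0.000121 with the preset correlation and adjusted p = 0.202 with an estimated correlation. All loci of the 3 chaperone lists rose within each batch as well, with 5 transcription factors up and 1 down in batch 1 and 7 up in batch 2. The response differed between batches for 4 small heat shock protein, 3 HSP90 and HSP100, 1 HSP70 and 7 transcription factor loci.

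Of the 7 dehydrin and LEA loci, proteins that accumulate in drying tissue, 3 rose with heat in drought leaves. So did 4 of 9 drought regulators, while 1 regulator fell. Both lists were called with the preset correlation (adjusted p = 0.00292 and 0.0137) but had adjusted p = 0.3 with an estimated correlation. Of 11 abscisic acid loci 1 rose, and none when adjusted over the list alone. Within batches this list went opposite ways: 6 members fell in batch 1, 9 rose in batch 2, and the heat response of 10 members differed between batches. LOC_Os07g05940, the member called in the pooled test, was at 0.155 CPM in the D40 pools of batch 1 and at 120.7 CPM in those of batch 2 (means, n = 2 each), and its log2 change within batch 1 was -1.39. Of the clock loci 3 fell, as did the chlorophyll breakdown locus LOC_Os03g21060. No Calvin cycle, osmolyte or secondary wall locus passed the threshold. In batch 1 and batch 2 taken alone, 2 and 7 dehydrin and LEA loci and 2 and 7 drought regulators rose, 1 and 2 clock loci and 1 and 1 chlorophyll breakdown loci fell, and 0 and 1 Calvin cycle loci fell. The osmolyte locus fell in batch 1 and rose in batch 2. The response of 6 dehydrin and LEA, 5 drought regulator, 3 clock, 1 Calvin cycle and 1 osmolyte loci differed between batches. LOC_Os11g13980 had 0 counts in the D30 pools and 165 ± 202 CPM (SD, n = 4) in D40. The D40 mean was at least 99600-fold higher with a floor of 3 counts over the D30 pools. The SD exceeded that mean, so this fold does not hold for each pool. LOC_Os09g37910 fell from 58.6 ± 14.4 to 4.99 ± 0.248 CPM (SD, n = 4). In whole leaves 8646 of 25103 genes differed, 4171 higher and 4475 lower, and limma on the batch-corrected FPKM gave 2514 higher and 7479 lower. The counts were 5399 in batch 1 and 13082 in batch 2.

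**Figure D1:**
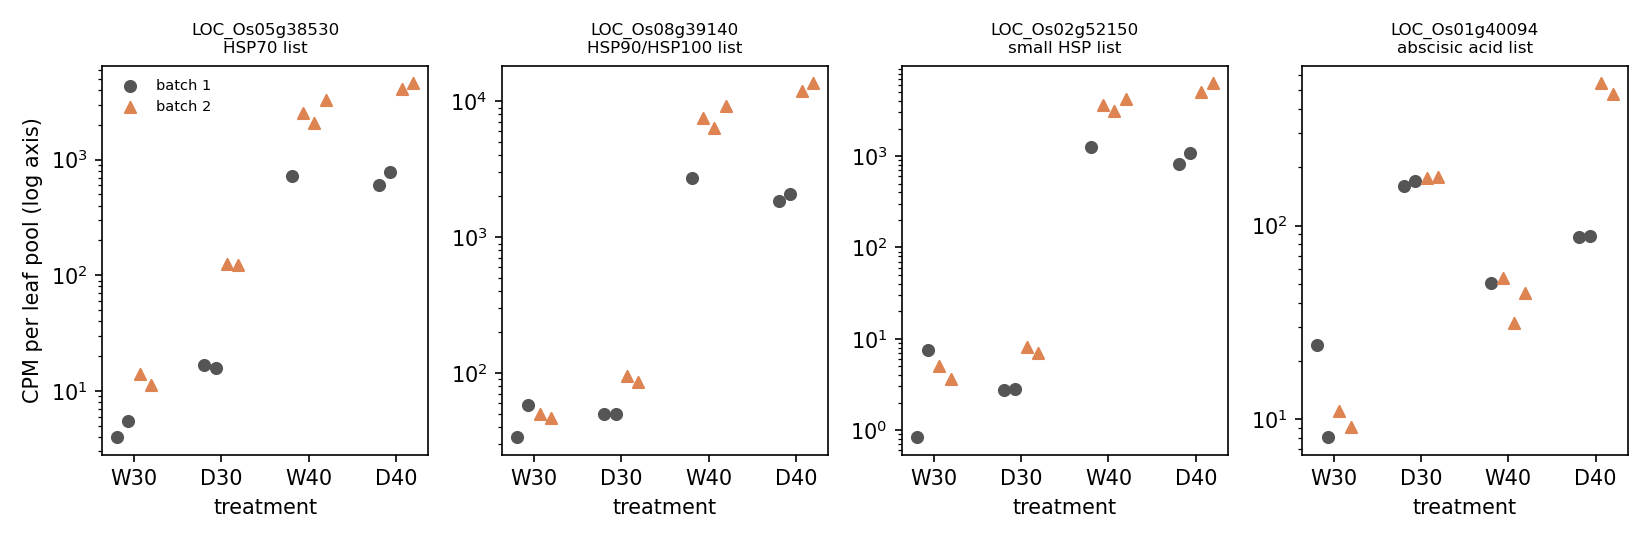
CPM per leaf pool (log axis) of 4 listed loci in the 4 treatments; each point is 1 pool, with circles for batch 1 and triangles for batch 2. For LOC_Os08g39140 the D40 pools of batch 1 lie at 1843 and 2069 CPM and those of batch 2 at 11910 and 13570 CPM.

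The heat responses of well-watered and drought leaves overlapped, and these comparisons share no library. In both, 2820 genes rose, where independent lists of these sizes would share 680.9, and 2809 fell, where 838.4 would be shared. Opposite calls were made for 19 and 13 genes. The 5629 genes called in the same direction made up 64% of those called in well-watered leaves, and their number was 2072 in batch 1 and 8852 in batch 2. Across genes, which are not independent replicates, the log2 changes had r = 0.69.

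Drought at 30 °C raised the listed abscisic acid loci. Abscisic acid is a hormone of the drought response, and of its 11 listed loci 9 rose, or 10 when adjusted over the list alone. LOC_Os09g15670 rose from 0.898 ± 0.643 to 43.7 ± 10.9 CPM (SD, n = 4), a log2 change of 6.05 with a standard error of 0.79 (edgeR adjusted p = 0.000501). In each batch taken alone 10 of the 11 members rose. The list had adjusted p = 1.8e-08, and adjusted p = 0.172 with an estimated correlation. Of 7 dehydrin and LEA loci 4 rose, or 6 when adjusted over the list alone, with list adjusted p = 0.000951 and adjusted p = 0.326 with an estimated correlation. LOC_Os11g26780 of that list was at 0.0387 ± 0.0672 CPM in W30 and at 14.9 ± 16.8 CPM in D30 (SD, n = 4), where the D30 pools were at 1.33 and 1.77 CPM in batch 1 and at 20.2 and 36.5 CPM in batch 2. The osmolyte locus LOC_Os05g38150 rose from 26.2 ± 5.79 to 79.6 ± 16 CPM (SD, n = 4), and it rose in each batch. Of the dehydrin and LEA loci 3 rose in batch 1, and 6 rose and 1 fell in batch 2. The drought response differed between batches for 4 abscisic acid and 2 dehydrin and LEA loci.

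Both HSP70 loci, 2 of 6 small heat shock protein loci and 1 of 9 heat stress transcription factors also rose with drought at 30 °C. LOC_Os05g38530 of the HSP70 list had a log2 change of 2.53 (standard error 0.29), and its list had adjusted p = 0.00287 and adjusted p = 0.172 with an estimated correlation. The small heat shock protein list had adjusted p = 0.0172 and adjusted p = 0.398 with an estimated correlation. Of the 3 Calvin cycle loci, which belong to carbon fixation, 1 fell: LOC_Os12g19381 went from 11110 ± 1500 to 6727 ± 1670 CPM (SD, n = 4). The clock locus LOC_Os08g06110, 1 of 7, rose by 0.89 on the log2 scale (standard error 0.20). None of the 9 drought regulators, 4 HSP90 and HSP100 loci, 2 chlorophyll breakdown loci or 3 secondary wall loci passed the threshold. For 3 uncalled lists the signs parted: the drought regulators had a median log2 change of -0.18, a mean of 0.32 and a downward camera direction, the HSP90 and HSP100 list 0.26, -0.06 and upward, and the clock list -0.00362, 0.12 and upward. In batch 1 and batch 2 taken alone, 1 and 5 small heat shock protein loci, 1 and 3 HSP90 and HSP100 loci, 1 and 2 HSP70 loci, 1 and 4 transcription factors, 0 and 3 secondary wall loci and 0 and 1 chlorophyll breakdown loci rose. Of the Calvin cycle loci 0 and 2 fell. Of the drought regulators 1 rose in batch 1, and 1 rose and 4 fell in batch 2. Of the clock loci 1 rose and 1 fell in batch 1 and 2 rose in batch 2. The drought response differed between batches for 3 secondary wall, 2 HSP90 and HSP100, 2 transcription factor, 1 HSP70, 1 small heat shock protein and 1 drought regulator loci. In whole leaves 2580 genes differed, 1323 higher and 1257 lower. The counts were 1728 in batch 1 and 8458 in batch 2. Leaving out 1 pool gave 1356 without W30 replicate 3, 1166 without W30 replicate 4, and 1678, 1702, 1708 and 1496 without D30 replicates 1 to 4.

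At 40 °C, listed abscisic acid and dehydrin loci were higher in drought than in well-watered leaves with both batches fitted and in batch 2, while batch 1, with 1 W40 pool, called none. Of the 11 abscisic acid loci 9 were higher, with list adjusted p = 2.34e-06 and adjusted p = 0.202 with an estimated correlation, and 6 of 7 dehydrin and LEA loci were higher, with adjusted p = 6.87e-07 and adjusted p = 0.193 with an estimated correlation. LOC_Os03g44380 of the abscisic acid list was at 1.44 ± 0.988 CPM in W40 and 29.2 ± 23.4 CPM in D40 (SD, n = 4). LOC_Os11g26780 was at 0.0211 ± 0.0124 CPM in W40 and 86.1 ± 98 CPM in D40 (SD, n = 4). In batch 1 alone 0 abscisic acid loci were called (median log2 change 0.22) and in batch 2 alone 9 were higher (3.55), and the difference between treatments parted by batch for 9 of the 11. For the dehydrin and LEA loci 0 and 7 were called (1.71 and 6.83), with 4 parting by batch. LOC_Os03g44380 was at a mean of 9.70 CPM in D40 against 2.89 CPM in the W40 pool of batch 1, and at 48.7 against 0.954 CPM (means) in batch 2. Of 6 small heat shock protein loci 3 were higher in D40, with list adjusted p = 0.000292 and adjusted p = 0.202 with an estimated correlation, while no HSP70, HSP90 and HSP100, heat stress transcription factor, drought regulator or chlorophyll breakdown locus passed the threshold. In batch 2 alone all 6 small heat shock protein, 2 HSP70, 4 HSP90 and HSP100 and 2 chlorophyll breakdown loci were higher in D40, as were 5 of 9 transcription factors and 4 of 9 drought regulators, with 1 and 2 lower. Batch 1 alone called 0 loci in each of these lists. The difference parted by batch for 3 drought regulator, 2 transcription factor and 2 HSP90 and HSP100 loci.

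With both batches fitted, all 3 secondary wall loci were higher in D40 than in W40, among them LOC_Os01g54620 at 3.13 ± 2.86 against 0.213 ± 0.0324 CPM (SD, n = 4), and their list had adjusted p = 0.00478 and adjusted p = 0.202 with an estimated correlation. The osmolyte locus LOC_Os05g38150 was at 89.5 ± 49.8 against 31.8 ± 6.14 CPM (SD, n = 4). In batch 1 it was at a mean of 46.5 CPM in D40 and at 40.9 CPM in W40 (log2 change 0.18, not called), and in batch 2 at means of 132.6 and 28.7 CPM (2.19), a difference between batches that was called. Of 7 clock loci 1 was higher, with list adjusted p = 0.0217 and adjusted p = 0.193 with an estimated correlation, and of 3 Calvin cycle loci 1 was lower, with list adjusted p = 0.0489 and adjusted p = 0.31 with an estimated correlation. Batch 2 alone called all 3 secondary wall loci and 4 clock loci higher and all 3 Calvin cycle loci lower, batch 1 alone called none of these, and 2 secondary wall and 2 clock loci parted by batch. In whole leaves 3547 genes differed, 2100 higher and 1447 lower. Batch 1, with 1 W40 pool, gave 1 gene and batch 2 gave 12265. Leaving out 1 pool gave 6092, 2136, 1481 and 1366 genes without W40 replicates 1 to 4, 1551 without D40 replicate 3 and 1174 without D40 replicate 4.

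Whether drought changed the heat response was tested as the interaction of soil water and temperature. When adjusted over the list alone, 5 loci of 4 lists were called. Both loci of the HSP70 list rose less with heat in drought leaves, with a log2 interaction of -2.10 (standard error 0.40) for LOC_Os05g38530 and -0.63 (standard error 0.26) for LOC_Os11g47760, and so did the transcription factor LOC_Os09g35790 (-1.55, standard error 0.27). The dehydrin and LEA locus LOC_Os03g20680 (5.71, standard error 1.37) and the secondary wall locus LOC_Os10g32980 (7.33, standard error 2.64) had interactions the other way, at low levels. LOC_Os03g20680 was at means of 0.941, 0.0728, 0.255 and 1.25 CPM in W30, W40, D30 and D40, with 0.0901 CPM in the D40 pools of batch 1 and 2.40 CPM in those of batch 2, and its interaction was called in batch 2 alone (7.50) and not in batch 1 (1.59). LOC_Os10g32980 was at means of 0.137, 0.00972, 1.60 and 2.52 CPM, and its interaction was called in neither batch (6.91 and 3.37). Over all genes none of the 5 was called (edgeR adjusted p = 0.077, 0.382, 0.077, 0.145 and 0.314, in the order of naming). LOC_Os05g38530 was at -1.83 in batch 1, where it was not called, and at -2.59 in batch 2, where it was, and LOC_Os11g47760 at -0.92 and -0.45, called in neither. LOC_Os05g38530 was at 8.69 ± 4.75 CPM in W30, 70.6 ± 62.7 in D30, 2142 ± 1070 in W40 and 2510 ± 2110 in D40 (SD, n = 4). LOC_Os09g35790 was at 9.81 ± 2.46, 31.7 ± 6.15, 629.8 ± 172 and 644.2 ± 310 CPM in the same order (SD, n = 4). For both loci the smaller rise went with a higher unheated mean in drought leaves and not with a lower heated mean. The HSP70 list is meant in what follows. The list had adjusted p = 0.00189 and adjusted p = 0.108 with an estimated correlation, and no other list passed the threshold. Signs parted for 3 of these: the small heat shock proteins had a median log2 interaction of 0.50, a mean of 1.56 and a downward camera direction, the HSP90 and HSP100 list -0.03, 0.77 and downward, and the drought regulators 0.04, -0.03 and upward. The median of the Calvin cycle list was 0.02 and its mean -0.07. Within batches the abscisic acid list parted: 6 of 11 members had a negative interaction in batch 1, 3 had a positive and 1 a negative one in batch 2, and 7 differed between batches. Batch 1 called 1 other listed locus, of the dehydrin and LEA list (negative). Batch 2 called 2 dehydrin and LEA, 2 drought regulator, 1 clock, 1 osmolyte, 1 transcription factor and 1 HSP90 and HSP100 loci with a positive and 2 transcription factor, 2 HSP90 and HSP100, 1 HSP70 and 1 small heat shock protein loci with a negative interaction. Of 25103 genes, 0 passed the threshold with edgeR and a batch term shared by all treatments. The smallest adjusted p was 0.0519, 2841 genes had an unadjusted p under 0.05, DESeq2 called 471, limma voom on 80 libraries 741 and limma on FPKM 404. Separate means for each treatment and batch also gave calls, though they rest on a single W40 pool in batch 1. Within batch 1 the test called 123 genes and within batch 2 it called 4281. Leaving out 1 pool gave 769 genes without W40 replicate 1, 14 without W30 replicate 2, 3, 2 and 3 without D40 replicates 1, 3 and 4, and 0 for every other pool.

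Listed chaperones rose along the whole blade. In each of the 5 segments all 4 HSP90 and HSP100 loci and both HSP70 loci rose with heat in well-watered and in drought leaves. LOC_Os08g39140 changed by 6.34 in segment 2 and 6.57 in segment 6 of well-watered leaves (log2, standard errors 0.66 and 0.31), and by 6.17 and 6.43 in drought leaves (0.64 and 0.31). All 6 small heat shock protein loci rose in every segment, except that 5 did in segment 2 of well-watered leaves. Of 11 abscisic acid loci, 7 rose with drought at 30 °C in segments 2 and 3 and 8 in segments 4, 5 and 6. LOC_Os05g38530 rose with drought in each segment, by 2.00 in segment 2 and 2.63 in segment 6 (log2), a difference between segments called when adjusted over the list alone and not over all genes (edgeR adjusted p = 0.334). Of 7 dehydrin and LEA loci, 3, 5, 4, 5 and 6 rose with drought in segments 2 to 6. The test of a difference between segments called none of these 7 over all genes and 1, LOC_Os02g44870, when adjusted over the list alone.

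Over all genes, heat altered 6984, 6974, 5652, 5941 and 5719 genes in segments 2 to 6 of well-watered leaves and 5513, 5959, 6202, 6480 and 6213 in those of drought leaves. Drought at 30 °C altered 1201, 1591, 1622, 1566 and 1751. In batch 1 alone the counts of well-watered heat were 1499, 2033, 3142, 688 and 2566, those of heat under drought 2669, 3237, 3277, 1976 and 4740, and those of drought 1380, 1077, 1051, 670 and 1130. In batch 2 alone they were 10358, 10905, 9657, 9051 and 9222, then 9262, 9891, 9550, 9308 and 8572, then 4985, 6140, 5397, 5332 and 5604. Of 21075 genes tested in every segment, 1779 rose and 1492 fell in all 5 with heat in well-watered leaves, 1922 and 1518 with heat in drought leaves, and 309 and 259 with drought. Without W30 replicate 4 the drought counts were 503, 746, 703, 728 and 775 and without W30 replicate 3 they were 593, 817, 828, 781 and 977, and single D30 pools left out gave 664 to 1058 where they moved a count by over 1.5 times. Well-watered heat fell to 4615, 4617, 3726 and 3813 in segments 2 to 5 without W30 replicate 4, to 3632 and 3960 in segments 4 and 5 without W30 replicate 3, and heat under drought to 3526 and 3955 in segments 2 and 3 without D40 replicate 3.

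**Figure D2:**
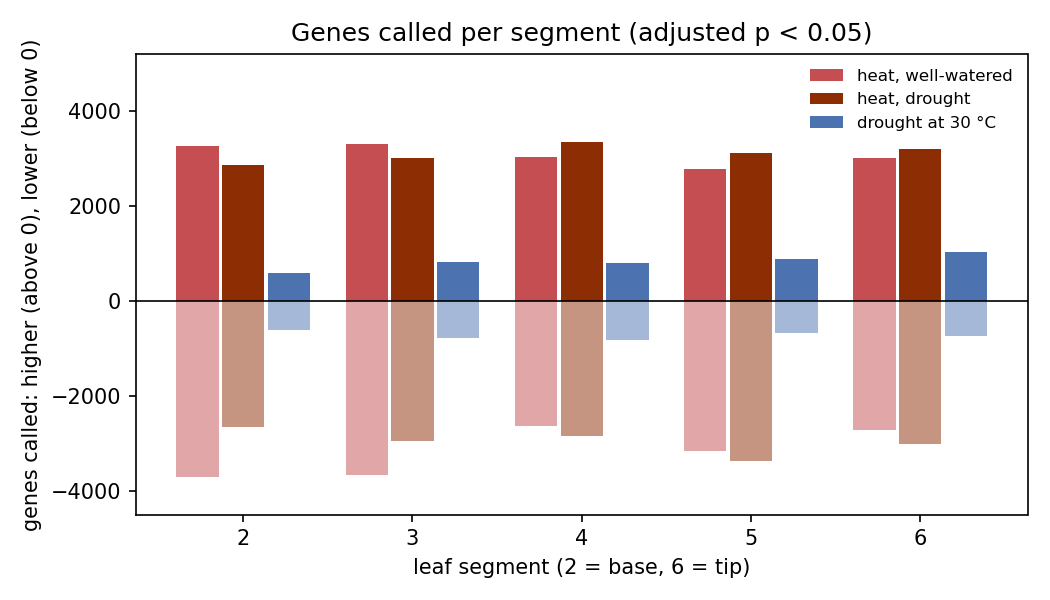
Genes called per leaf segment (horizontal axis, base to tip) with edgeR; solid bars above 0 count genes that were higher and pale bars below 0 genes that were lower. In well-watered leaves heat altered 6984 genes in segment 2 and 5719 in segment 6, and in drought leaves 5513 and 6213.

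Within single segments the interaction called few genes, and those given here are named only because they were called. In segment 6 the HSP70 locus LOC_Os05g38530 rose less with heat in drought leaves (log2 interaction -2.17, standard error 0.32, edgeR adjusted p = 0.0359), along with LOC_Os03g09940 (-2.13) and LOC_Os08g34500 (-3.32), while LOC_Os06g19430 was at 2.44. In segment 3 LOC_Os03g51920 (-4.39), LOC_Os09g28340 (-2.25) and LOC_Os06g03800 (1.48) were called. These 7 loci were chosen after their values were seen. Segments 2, 4 and 5 gave 0 genes with edgeR. Without the batch term, and with a replicate block across treatments, segments 3 and 6 gave 0 as well, so all 7 calls were lost. At an unadjusted p under 0.05 there were 1979, 2094, 2014, 1656 and 2211 genes in segments 2 to 6, and DESeq2 called 222, 225, 181, 128 and 246. Batch 1 alone gave 162, 100, 65, 7 and 86 and batch 2 alone 1739, 2660, 1968, 1102 and 1070. Without W40 replicate 1 the counts were 42, 209, 63, 12 and 344, and without W30 replicate 2 segment 3 gave 18. Leaving out any other pool gave 0 to 3 in segments 2, 4 and 5, and in segment 3 the count was 0 without D30 replicates 1 or 2, W40 replicates 2, 3 or 4 or D40 replicate 2 and 1 without W30 replicate 3. In segment 6 it was 0 without W30 replicate 4, 1 without W30 replicates 1 or 3, D30 replicates 1 or 3, W40 replicate 4 or D40 replicate 2, and 2 without D30 replicates 2 or 4 or D40 replicates 1 or 3.

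Along the unstressed blade, all 3 secondary wall loci were lower in the tip-side segment 6 than in the base-side segment 2, LOC_Os09g25490 by a log2 change of -3.82. Among these 3, LOC_Os10g32980 was at only 0.137 ± 0.126 CPM in whole W30 leaves (SD, n = 4). Lower toward the tip as well were 2 of 3 Calvin cycle loci, among them LOC_Os12g17600 (-0.58), and the osmolyte locus (-0.48). Of 11 abscisic acid loci 2 were higher toward the tip and 2 lower, and LOC_Os09g28390 was higher by 1.20 (edgeR adjusted p = 3.42e-09). Of 9 heat stress transcription factors 3 were higher and 1 lower, and LOC_Os09g35790 was higher by 0.89. The drought regulator LOC_Os11g08210 was higher by 0.96, 1 of 2 called of 9, and the chlorophyll breakdown locus LOC_Os03g21060 by 0.81. Of 7 clock loci 2 were higher and 1 lower, and of 7 dehydrin and LEA loci 1 was higher and 1 lower. Of 4 HSP90 and HSP100 loci 1 was higher, LOC_Os09g30412 by 0.58 (edgeR adjusted p = 8.49e-07), and 1 was lower, LOC_Os04g01740 (log2 change -3.48, edgeR adjusted p = 0.00221). Of 6 small heat shock protein loci 1, LOC_Os03g14180, was lower (-3.57), and no HSP70 locus passed the threshold. The levels of LOC_Os04g01740 and LOC_Os03g14180 were low and uneven among the W30 pools, as given below, so their large changes are uncertain. In all, 7459 of 23888 genes differed, 4094 higher and 3365 lower, with 5962 in batch 1 and 6968 in batch 2.

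Whether responses differed along the blade was tested over all segments at once. A call means that the effect parted between the 5 segments beyond the scatter of single libraries, which were taken as independent within a pool. Slopes along the blade that part between pools were not modelled as such. With limma voom, other splits of the pools called up to 2816, 2032 and 1808 genes. The real split called 475, 42 and 639 for heat in well-watered leaves, heat in drought leaves and drought. A call can therefore also come from differences between pools. The log2 values give its estimate in segment 6 minus that in segment 2, a pair not tested alone. In well-watered leaves the heat effect on LOC_Os03g14180, not called in whole leaves, and on LOC_Os04g01740 differed between segments (3.67 and 2.66). Their W30 levels were low and uneven, at 0.00420 to 0.780 CPM for LOC_Os03g14180 and 0.00254 to 2.27 CPM for LOC_Os04g01740 over the 4 pools. The heat effect also differed between segments for LOC_Os09g28390 and LOC_Os03g16170 of the abscisic acid list (-1.40 and -0.93), the drought regulators LOC_Os11g08210 (-0.90) and LOC_Os01g07120 (-0.65) and the transcription factor LOC_Os09g35790 (-0.92). The drought effect at 30 °C differed between segments for LOC_Os01g40094 of the abscisic acid list (0.87) and for LOC_Os04g01740 (3.09), which was not called in whole leaves. For the heat response of drought leaves and for the dependence of the interaction on segment no listed locus was called over all genes. When adjusted over the list alone, the first test called the small heat shock proteins LOC_Os01g04360 (1.56) and LOC_Os01g04370 (1.72), LOC_Os05g44340 of the HSP90 and HSP100 list (1.04) and the transcription factor LOC_Os10g28340 (0.47). The second called LOC_Os09g28390 (1.42) and LOC_Os03g16170 (1.06) of the abscisic acid list, the drought regulator LOC_Os01g07120 (1.05) and LOC_Os04g01740 (-2.02). This adjustment added 1 drought regulator, 1 transcription factor, 1 HSP70 and 1 HSP90 and HSP100 locus to the heat response of well-watered leaves, and the osmolyte locus, besides LOC_Os02g44870 and LOC_Os05g38530, to the drought response.

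Over all genes, 352 of 23888 differed between segments in their heat response in well-watered leaves, 25 in drought leaves, 242 in their drought response and 16 in the interaction. In batch 1 alone these counts were 205, 205, 326 and 35, and in batch 2 alone 800, 33, 2400 and 80. Leaving out 1 pool moved most of them. The first was 1131, 195, 143 and 119 without W40 replicates 1 to 4. The second was 5, 12 and 6 without D30 replicates 1, 2 and 4, and 8, 13 and 40 without D40 replicates 1, 3 and 4. The third was 435, 780, 86 and 80 without W30 replicates 1 to 4, and 149, 118 and 82 without D30 replicates 2 to 4. The last was 6, 32, 31 and 9 without W30 replicates 1 to 4, 4 and 6 without D30 replicates 3 and 4, 175, 9, 8 and 4 without W40 replicates 1 to 4, and 2, 6 and 9 without D40 replicates 1, 2 and 4.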

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

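The tests of mixed tissue and of the clock were chosen only after the results they bear on had been seen, and the tests of depth after the pooled counts with thinned pools, though not the values they measure, had been seen.

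The heat response differed between batches. In drought leaves, 6883 genes responded differently to heat in batch 2 than in batch 1, and in well-watered leaves 5931. Sequencing depth is argued against: with all pools thinned to the smallest total, 6961 genes differed in drought leaves. Unheated tissue mixed into the heated pools of batch 1 stays open as a part of the difference, but not as an account of every locus. Of 11 abscisic acid loci, 6 fell with heat in batch 1 and 9 rose in batch 2 (median log2 changes -0.915 and 1.61). Mixing gives levels between the unheated and the heated one. Where the heated level lies above the unheated level of batch 1, such falls argue against mixing for these loci. Over 2132 genes raised by heat in batch 2 the implied share of heated tissue had quartiles of 2.55% and 29.7%, but how uneven that is depends on whether the heated or the unheated share is taken, so it decides nothing. Of 2087 such genes that mixing would raise in batch 1 whatever the share, 1043 were called higher there and 110 lower. The lower ones were 9.54% of the calls, above the 5% of false calls that mixing allows and short of the 10% set as the bound against it. A different phase of the daily clock in batch 1 may contribute: in unheated pools 5 of 7 clock loci differed between batches, LOC_Os08g06110 being 3.15 log2 units higher in batch 2 and 4 others lower, while 40.2% of all genes differed. The labels give 1 collection time for all, and since batch also holds every other difference of growth and handling, clock phase and these cannot be told apart.

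With both batches and a batch term shared by all treatments, the drought by heat interaction called 0 genes, and in batch 2 alone it called 4281. That fit does not let a response differ between batches, so the 0 holds for that fit only. A fit with a separate mean for each treatment and batch, which rests on 1 W40 pool in batch 1, did call genes. Depth is argued against, since the batch 2 pools thinned to the smallest total gave 4316. With limma voom, 3 of 100 splits of the batch 2 pools over the treatments, the real one included, called as many genes as the real 4058, and the highest other called 13197. These splits put heated and unheated pools into 1 group, so the heat effect enters their residuals or the tested term. Neither their share nor this high count therefore bears on chance or on another structure of these 9 pools, and chance stays open. Across genes, the log2 interactions in batch 1 and batch 2 had r = 0.000231. For the heat response the r between batches was 0.497 in well-watered leaves and 0.463 in drought leaves. These values show no interaction pattern common to both batches, though those of batch 1 rest on 1 W40 pool. A biological interaction, untested here apart from batch and from the leaf age that came with soil water, stays open.

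The other splits of the samples, all by limma voom, are given for each count. For heat in well-watered leaves the real split called 9108 genes and the highest of the other 34 called 1020, and for heat in drought leaves 8806 and 659. For drought at 40 °C it called 3730 against 2584, and across genes its log2 changes in batch 1 and batch 2 had r = 0.213. In these 3 results 1 of 35 splits (2.86%), the real one, was as large, the smallest share that 35 splits can give. Taken singly, each such share argues against chance but does not exclude it. The results reuse the same pools, and no adjustment was made over them. For drought at 30 °C, 2 of 35 splits were as large: the real one called 3015 and the split that put both treatments' batch 1 pools together called 3488. That split follows the batch. Its batch term rests on the heated pools alone, so it measures how the batch difference of unheated pools departs from theirs. It is therefore no plain draw of chance, and the share cannot decide on chance, which is not excluded for this count. For the whole-leaf interaction, 4 of 100 splits were as large as the real 3 genes and the highest other called 7041. Since these splits too mix heated and unheated pools, they leave chance open for the interaction. Batch 1 alone gave 123 genes and batch 2 alone 4281 with edgeR. In segments 2 to 6 the real heat split called 7009, 7065, 5943, 6469 and 5965 genes in well-watered leaves, with 212, 2583, 981, 21 and 432 the highest others, and 5835, 6379, 6316, 6513 and 6505 in drought leaves, with 228, 322, 186, 141 and 832. In all 10 only the real split was as large, which bears on chance in the same way. For drought at 30 °C the real split called 1401, 1885, 1904, 1930 and 2187 and the batch split 1671, 2124, 2364, 1553 and 2257. In segments 2, 3, 4 and 6, 2 of 35 were as large, the real one and the batch split. For the same reason this share cannot decide on chance, which is not excluded there. In segment 5 only the real one was, again the smallest share possible. Within batches the drought counts were 1728 and 8458 in whole leaves. The interaction per segment called 2, 4, 0, 0 and 10, and as many were called by 4, 2, 100, 100 and 2 of 100 draws, with 4084, 5219, 5210, 5322 and 4922 the highest others. These draws mix heated and unheated pools as well and leave chance open in all 5 segments, and the heat effect in the tested term can give such high counts by itself. For the gradient the 8 ways of swapping segments 2 and 6 within pools are too few for a share under 0.05. The real count was 8262 and the highest other 3263.

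The response to heat depended on segment for 352 genes in well-watered and 25 in drought leaves, the response to drought for 242 genes, and the interaction for 16, each a tested difference between segments. With limma voom 6, 8 and 4 of 35 splits and 35 of 100 draws called as many genes as the real 475, 42, 639 and 17. The highest others called 2816, 2032, 1808 and 2341, and each of the first 3 of these put all batch 1 pools on one side, together with W40 replicate 2 in the first. Chance cannot be excluded for the first 3, and these splits, which call several times the real count, point to a structure of the pools along the batch. The draws for the interaction mix heated and unheated pools and leave chance open. Within batch 1 and batch 2 the tested counts were 205 and 800, 205 and 33, 326 and 2400, and 35 and 80.

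Pool totals and named loci, each within 1 treatment, made 67 groups of 4 values that were examined for 1 pool far from the rest. In 4 groups there was one, where chance alone gives about 1 in 20 for a single group. The groups reuse the same 16 pools and are not independent, so this share is no test. W40 replicate 1, the only W40 pool of batch 1, stood apart for the clock loci LOC_Os02g40510 (gap over range 0.994) and LOC_Os11g05930 (0.962) and for the osmolyte locus LOC_Os05g38150 (0.886). A batch difference alone would set this pool apart, so the pool and its batch cannot be told apart here. W30 replicate 3 stood apart for LOC_Os11g26780 (0.925).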

How the results depend on the processing

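Treatment by batch cell means, halved counts, thinned pools, single batches per segment and in segment tests, and the segment by batch term were chosen after seeing the data. The values are counts of genes called, with edgeR where no tool is named, wherever these moved by over 1.5 times, and counts not given stayed within that. Fitting only the 2 treatments compared gave 4420 for drought at 30 °C. With limma voom on 80 libraries with pool as a random effect there were 4899 for drought at 30 °C, 5431 for drought at 40 °C and 741 for the interaction. The DESeq2 Wald test gave 4251 for drought at 30 °C, 5610 for drought at 40 °C, 471 for the interaction and 2356, 2809, 2799, 2779 and 3066 for drought at 30 °C in segments 2 to 6. It also gave 222, 225, 181, 128 and 246 for the interaction in segments 2 to 6. DESeq2 size factors gave 1 for the interaction in segment 3 and 9 for the interaction by segment. Batch 1 alone gave 3308 for heat in well-watered leaves, 5399 for heat in drought leaves, 1 for drought at 40 °C and 123 for the interaction. It also gave 1499, 2033, 3142, 688 and 2566 for heat in well-watered leaves in segments 2 to 6, 2669, 3237, 3277 and 1976 for heat in drought leaves in segments 2, 3, 4 and 5, 1051, 670 and 1130 for drought at 30 °C in segments 4, 5 and 6 and 162, 100, 65, 7 and 86 for the interaction in segments 2 to 6. It also gave 205 for well-watered heat by segment, 205 for drought-leaf heat by segment, 35 for the interaction by segment and 2072 for the overlap of the heat responses. Batch 2 alone gave 13478 for heat in well-watered leaves, 13082 for heat in drought leaves, 8458 for drought at 30 °C and 12265 for drought at 40 °C. It also gave 4281 for the interaction, 10905, 9657, 9051 and 9222 for heat in well-watered leaves in segments 3, 4, 5 and 6, 9262, 9891 and 9550 for heat in drought leaves in segments 2, 3 and 4 and 4985, 6140, 5397, 5332 and 5604 for drought at 30 °C in segments 2 to 6. It also gave 1739, 2660, 1968, 1102 and 1070 for the interaction in segments 2 to 6, 800 for well-watered heat by segment, 2400 for drought by segment and 80 for the interaction by segment. It also gave 8852 for the overlap of the heat responses. On the batch-corrected FPKM limma gave 404 for the interaction. The batch-corrected counts gave 171 for the interaction, 8, 25, 12, 33 and 36 for the interaction in segments 2 to 6, 225 for well-watered heat by segment and 40 for drought-leaf heat by segment. They also gave 3 for the interaction by segment. Halved counts gave 3 for the interaction. With limma voom there were 42 for drought-leaf heat by segment and 639 for drought by segment. A linear trend over segments gave 1393 for well-watered heat by segment, 144 for drought-leaf heat by segment, 1524 for drought by segment and 247 for the interaction by segment. Leaving out the batch term gave 5734 for heat in well-watered leaves, 4510 for heat in drought leaves, 638 for drought at 30 °C and 1185 for drought at 40 °C. It also gave 4563, 4587, 3766 and 3589 for heat in well-watered leaves in segments 2, 3, 5 and 6, 2598, 3056, 3442, 3483 and 3017 for heat in drought leaves in segments 2 to 6, 219, 423, 386, 395 and 385 for drought at 30 °C in segments 2 to 6 and 0 and 0 for the interaction in segments 3 and 6. It also gave 3015 for the overlap of the heat responses. No expression filter gave 4 for the interaction and 1, 14, 5, 13 and 18 for the interaction in segments 2 to 6. Segment tests with no replicate block, here the leaf pool, gave 2231 for the leaf gradient, 0 for well-watered heat by segment, 0 for drought-leaf heat by segment and 0 for drought by segment. They also gave 0 for the interaction by segment. The replicate block across treatments gave 5699 for heat in well-watered leaves, 1414 for drought at 30 °C, 1039 for drought at 40 °C and 4194, 4219, 3411, 3745 and 3379 for heat in well-watered leaves in segments 2 to 6. It also gave 525, 871, 828, 932 and 939 for drought at 30 °C in segments 2 to 6 and 0 and 0 for the interaction in segments 3 and 6. A segment by batch term gave 524 for drought by segment. Treatment by batch cell means gave 13410 for heat in drought leaves, 8164 for drought at 30 °C, 7826 for drought at 40 °C and 1459 for the interaction. They also gave 9047 for the overlap of the heat responses. With 1 pool left out at a time the counts ran over 503 to 1394, 746 to 2259, 703 to 2077, 728 to 1863 and 775 to 1930 for drought at 30 °C in segments 2 to 6, 1166 to 3027 for drought at 30 °C, 1174 to 6092 for drought at 40 °C and 2 to 175 for the interaction by segment. They ran over 0 to 42, 0 to 209, 0 to 63, 0 to 12 and 0 to 344 for the interaction in segments 2 to 6, 0 to 769 for the interaction, 80 to 780 for drought by segment and 5 to 40 for drought-leaf heat by segment. They ran over 119 to 1131 for well-watered heat by segment, 3526 to 5711, 3955 to 6154, 4253 to 6709, 4653 to 6499 and 4486 to 6065 for heat in drought leaves in segments 2 to 6, 6351 to 8795 for heat in drought leaves and 4615 to 7261, 4617 to 7953, 3632 to 6581, 3813 to 6223 and 3979 to 7199 for heat in well-watered leaves in segments 2 to 6. They ran over 6174 to 9836 for heat in well-watered leaves and 5244 to 6829 for the leaf gradient. Of 23 list tests called with the preset correlation, 7 were with the estimated one. For 34 pairs of a listed locus and a comparison, 666 alternative values kept direction and call, 81 over 18 pairs kept direction without the call, and 1 reversed: LOC_Os07g05940 with heat in drought leaves was at -1.39 in batch 1 alone. Across treatments the replicate numbers followed batch: 21 of 24 same-numbered pairs of pools deviated together at r over 0.1 before batch was taken out and 2 of 24 after it (-0.496 to 0.171), so the numbers were not taken to pair pools. Fewer pools entered the fits of single batches and with a pool left out. Yet batch 2 alone called more genes than all pools did in each whole-leaf comparison, for drought at 30 °C 8458 against 2580. The smaller number of pools therefore does not account for these rises. What moved the counts was not tested for any setting. On batch-corrected FPKM 29.2% of the calls for heat in well-watered leaves and 25.2% of those in drought leaves were higher, against 46.6% and 48.2% on raw counts. The batch-corrected counts gave 50.9% and 53.1%, so the batch correction alone does not give the lower shares. The FPKM fit also had no TMM scaling, which was not tested by itself. Values of loci near 0, such as LOC_Os11g26780 in W30, rest on few reads. Thinned pools and halved counts were among the alternatives for the 34 pairs, which include this locus with drought. The effect of depth on loci near 0 was not examined apart from the other pairs. Recovery in simulation, which did not vary depth, fell to 7.07% for an interaction of 1 log2 unit.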

Other observations

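The test of these loci was the difference between batches of a response, computed after the batches were seen to part; the loci were chosen after their values were seen.

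Listed groups outside the chaperones also parted by batch. All 3 secondary wall loci, which belong to cell wall thickening, differed between batches in their drought response at 30 °C. LOC_Os09g25490 was at 0.0428 and 0.119 CPM in the D30 pools of batch 1 and at 1.1 and 6.02 CPM in those of batch 2, and LOC_Os01g54620 at 0.496 and 0.501 CPM and at 1.80 and 7.06 CPM. The dehydrin and LEA locus LOC_Os11g26780 was at 0.671 and 2.08 CPM in the D40 pools of batch 1 and at 162.3 and 179.2 CPM in those of batch 2. With heat in drought leaves the response of 6 of 7 dehydrin and LEA loci and of the osmolyte locus differed between batches, the osmolyte locus falling in batch 1 and rising in batch 2. The abscisic acid locus LOC_Os01g40094 was at 160.1 and 170.1 CPM in the D30 pools of batch 1 and 176.1 and 178.1 CPM in those of batch 2, but at 87.5 and 87.9 CPM and at 481.2 and 544.2 CPM in the D40 pools. Its drought response at 30 °C was not called as different between batches. The Calvin cycle locus LOC_Os11g47970 was at 1371 to 2389 CPM in the 4 unheated pools of batch 1 and at 9214 to 13620 CPM in those of batch 2. No explanation was tested for these values.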
